A study of Rattus norvegicus with 6 samples.

How the data were processed

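Polyadenylated RNA was sequenced from rat bone marrow mesenchymal stem cells, the adherent stromal cells of the marrow that can form bone, fat and cartilage cells. The series holds 6 libraries, 3 labelled young and 3 labelled aged, and the labels number the libraries of each group from 1 to 3 as biological replicates. The labels give no ages in months, sex, passage, culture condition or sequencing date, and do not say whether each library came from a separate animal. The p-values therefore measure only the spread between these libraries, which may be partly technical.

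Total RNA was extracted with TRIzol and libraries were made with a VAHTS Universal V6 RNA-seq kit, per the labels' protocols. The programs fastp, HISAT2 and HTSeq are named, without versions or settings, per the submitters' processing notes. The genome build, the annotation, the strand setting and any filter are not given in the sources used here. The authors deposited 1 table of raw read counts per gene symbol, with 1 column per library and no normalization. The values are whole numbers, the totals differ between libraries, and every row carries a gene symbol. Each column was matched to its sample through the library name that the labels give. Of the 21026 symbols, 19087 matched a current RefSeq symbol of assembly GRCr8 and 114 matched only a synonym. A further 1825 were unmatched, and 4992 symbols were placeholders beginning with LOC or RGD. Symbols were used as deposited, and no coordinates are printed because the files name no build. Without transcript sequences of the authors' annotation, GC content and transcript length could not be computed per gene. Because the strand setting is not given, reads of overlapping and antisense genes cannot be told apart. Families with near-identical copies or processed pseudogenes (ribosomal protein, ATP synthase subunit, interferon-induced and Y-linked genes) may share reads.

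Total counts ranged from 34638874 to 42479626 per library. A gene with 0 counts in a library could still have been present at up to 3 counts, which is 0.0688 to 0.0840 CPM (counts scaled to a common library total) depending on the library. Such limits, and the binomial intervals given for ratios of few counts, cover counting error only.

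Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default minimum count of 10, libraries were scaled by TMM, and aged was compared with young by the quasi-likelihood F test (glmQLFit, glmQLFTest) with group as the only term. P-values were adjusted by the Benjamini-Hochberg method over the 14273 genes tested, and genes with an adjusted p under 0.05 were called. CPM values are scaled by the TMM factors and given as mean ± SD over 3 libraries. Log2 fold changes are aged over young, and their standard errors are the fitted change divided by the square root of the F statistic. Where all 3 libraries of a group had 0 counts, a lower bound of the fold was computed against a floor of 3 counts per library, with the same TMM scaling. Where a group had 1 to 3 counts in all, the ratio of TMM-scaled counts is given with its 95% exact binomial interval, since fitted folds then depend on the prior count.

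Before the data were examined, 27 gene lists were fixed. They cover mitophagy, autophagy, cytosolic DNA sensing, interferon-stimulated genes, senescence, the secretory phenotype of senescent cells, the cell cycle, 3 differentiation lineages, stromal, matrix, Wnt and BMP genes, mitochondria, metabolism, stress, DNA repair, other cell types and Y-linked genes. The 26 lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, and adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The estimated setting also uses the few residual degrees of freedom, so a weaker p there does not measure correlation alone. For Wnt and BMP genes the estimated correlation was -6.5e-04, below the preset, yet the unadjusted camera p rose from 0.010 to 0.040. The rule for naming genes was also fixed then: the 6 largest rises and 6 largest falls among called genes with a mean CPM of at least 5, an informative symbol and no overlap between groups; the member of each list with the smallest p (2 members for the 8 lists closest to the study's theme); and 12 genes chosen in advance, of which 1 is not reported here. Other list members are named as examples chosen after their values were seen.

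Simulated counts served to test the procedure on the aged against young design. They used gene means over all 6 libraries, the real library sizes and the fitted dispersions. Of 14273 genes, 50 were changed at each fold, drawn among genes with a mean of at least 50 counts. The procedure recovered 66% of genes changed 1.25-fold, 80% at 1.5-fold, 96% at 2-fold and all 50 at 4-fold, and 7.07% of its calls were false. Most simulated genes were unchanged, whereas 86.4% of tested genes were called in the data. These rates therefore need not hold for the real comparison. In the same simulation camera called a list of 40 raised genes and did not call a list of 40 unchanged genes. Within-group pairs of libraries differed by more than counting noise, with a median squared difference of 3.01 to 7.63 times that expected, so each was counted as 1 sample. That does not show that they came from separate animals or RNA. The highest values, 7.63 and 6.28, came from the pairs with young replicate 2, and the other pairs lay at 3.01 to 3.54.

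Alternatives fixed in advance were RLE, upper-quartile and no scaling factors, no filter and a filter of CPM of at least 1 in 3 samples, DESeq2 1.42.0, limma-voom, the replicate number as a block, a 2-fold requirement, glmTreat against a log2 change of 0.58, the estimated correlation, fry, and leaving out each library. Intervals of the medians of the lists in the closing section come from 2000 bootstrap draws over genes. Fits without the 13 mitochondria-encoded genes and without the 20 most abundant genes were added after seeing the data.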

Results

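RNA sequencing compared rat bone marrow mesenchymal stem cells labelled young with those labelled aged, 3 libraries each. The series title names mitophagy, aberrant double-stranded DNA of the cell itself and bone healing in old age as the subject of the study. Totals were 40661348, 42479626 and 40180480 counts in the young libraries and 36786897, 38921547 and 34638874 in the aged ones. On average 16401 genes had at least 1 count in a young library and 17912 in an aged one. Mitochondria-encoded transcripts took 1.18% ± 0.157 of the counts in young libraries and 4.33% ± 0.113 in aged ones (SD, n = 3 each).

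The transcriptomes of the young and the aged cells differed almost throughout. Of 14273 tested genes, 6375 were higher and 5964 lower in aged cells (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), together 86.4% of all tested. A change of at least 2-fold was seen for 4200 of the higher and 3000 of the lower genes, and one of at least 8-fold for 1337 and 449. The first principal component of log2 CPM carried 94.5% of the variance and separated the groups. Correlations across genes were 0.991 to 0.993 between libraries of 1 group and 0.821 to 0.833 between groups, and genes are not independent replicates. In 87.5% of genes all libraries of one group lay above all of the other, where chance gives 10%. Scaling by library size alone raised all fold changes by a median of 0.34 on the log2 scale, and then 62.3% of called genes were higher instead of 51.7%. The medians of the senescence regulator, stromal, smooth muscle, antioxidant, DNA repair, immediate-early, and Wnt and BMP lists changed sign under that scaling, so no direction is given for them as groups relative to a fixed amount of RNA.

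By the naming rule fixed in advance, the largest rises in aged cells were in Cyp1a1, a cytochrome P450 of xenobiotic metabolism, and Ttn, the sarcomere protein titin. Cyp1a1 had 0 counts in every young library and 17.7 ± 1.12 CPM in aged cells, at least 215.5-fold higher. Ttn also had 0 young counts and reached 13.4 ± 0.962 CPM, at least 163-fold higher. Nalcn, a sodium leak channel, had 2 counts in all young libraries and 1696 in aged ones, a TMM-scaled ratio of 750.9 (95% interval 207.6 to 6206). Tmem132e, the chaperone gene Hspa4l and Fam180a were 329-fold, 209-fold and 192-fold higher, each with edgeR adjusted p of 1.7e-14 or less. These folds rest on 4, 14 and 36 counts in all young libraries. Over the alternative settings the log2 change of Tmem132e ran from 7.79 to 9.60. The largest falls by that rule began with Fabp4, the fatty acid-binding protein of adipocytes, which had 321 ± 10.2 CPM in young cells and 3 counts in all aged libraries, a TMM-scaled ratio of 13250 (95% interval 4533 to 64250). Prg4, which encodes lubricin, went from 308 ± 10.5 to 0.126 ± 0.113 CPM. Retn, which encodes resistin, had 16.1 ± 1 CPM in young cells and 0 aged counts, at least 221-fold lower. Trarg1, a regulator of glucose transporter traffic, the peptide transporter gene Slc15a3 and carbonic anhydrase gene Car3 each had 1 aged count, with young-to-aged ratios of 1530, 1466 and 1359 and lower interval ends of 274.2, 262.6 and 243.4. In a check added after seeing the data, all 35 tested genes of a list of long transcripts thought to be of low GC content rose, with a median log2 change of 3.53 (camera adjusted p = 4.3e-31, and adjusted p = 0.072 with an estimated correlation). GC content and length were taken from general knowledge there and were not measured. Their rises ran from 1.34-fold (Uaca) to 38.1-fold (Smc6). Large rises of single list members below, such as Usp15, Rb1cc1, Eif2ak2, Bmpr2 and Dnm1l, lie within that range. They were not tested apart from that pattern.

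**Figure D1:**
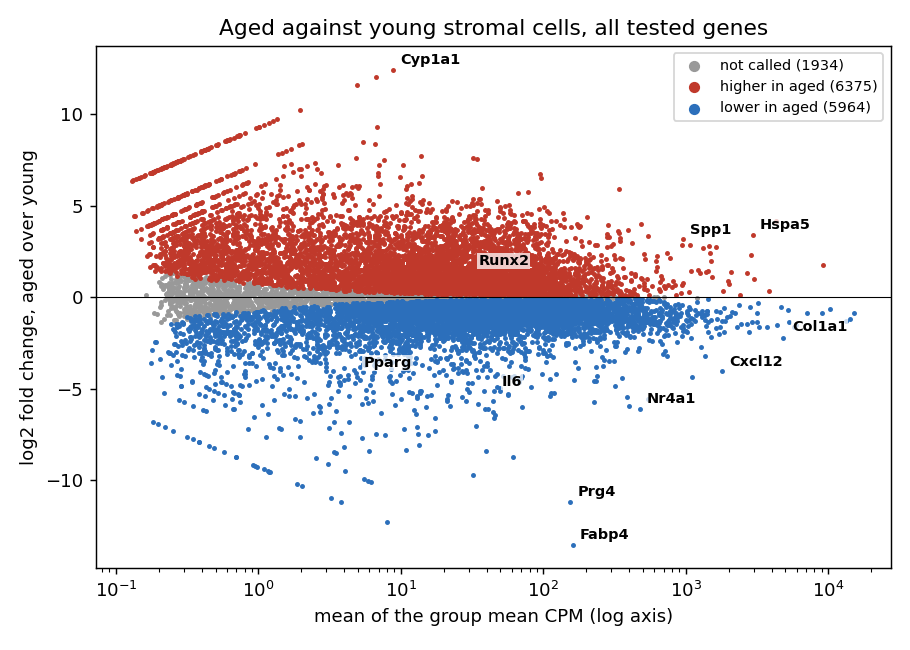
Log2 fold change (aged over young, edgeR fit) of each of the 14273 tested genes against mean CPM on a log axis, with genes higher in aged cells in red, lower in blue and not called in grey. Fabp4 has the lowest value and Cyp1a1 the highest, and the folds of genes at 0 counts in a group are fitted values that depend on the prior count.

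Cell cycle genes were lower in aged cells. Of 45 listed genes, 39 fell and 4 rose, with a median log2 change of -2.21, and 43 passed when adjusted over the list alone. Of all tested genes 86.4% were called, so a count of members passing does not by itself set this or any later list apart. Plk1, a mitotic kinase, fell from 111 ± 2.54 to 2.72 ± 0.422 CPM, 40.7-fold. Rrm2, a subunit of ribonucleotide reductase, fell 15.4-fold, Cdk1 fell 30.2-fold, and Birc5, which encodes survivin, fell 44.1-fold. The proliferation marker Mki67 fell 1.22-fold, 13.2 ± 0.847 against 10.9 ± 0.860 CPM (edgeR adjusted p = 0.011). Pcna, the sliding clamp of DNA replication, rose 1.85-fold, and Ccne2, a G1/S cyclin, rose 1.78-fold. Camera called the list lower with adjusted p = 1.4e-14, and adjusted p = 0.023 with an estimated correlation.

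Regulators of senescence changed in both directions, with 12 of 35 higher and 20 lower, and 32 passed when adjusted over the list alone. Cdkn1a, which encodes the cell cycle inhibitor p21, rose 2.26-fold from 269 ± 5.25 to 609 ± 3.72 CPM. Cdkn2a, which encodes p16 and p19ARF, fell 2.62-fold from 48.4 ± 1.12 to 18.5 ± 1.88 CPM. Ccnd1, encoding cyclin D1, fell 7.16-fold and Lmna, encoding lamin A/C, fell 3.88-fold. Lmnb1, encoding lamin B1, fell 30.5-fold, and the p53 targets Mdm2 and Gadd45a rose 5.09-fold and 4.39-fold. Camera did not call the list as a whole against other genes (adjusted p = 0.51). Here and below, a list that was not called may still differ from other genes. The median of the senescence list, -0.21, became 0.12 when libraries were scaled by size alone.

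Genes of the secretory phenotype of senescent cells were mostly lower in aged cells. Among 45 tested genes, 33 fell and 10 rose, with a median log2 change of -1.29, and 44 passed when adjusted over the list alone. Il6 fell 35.3-fold, from 88.2 ± 8.43 to 2.48 ± 0.287 CPM. The neutrophil chemokine genes Cxcl1 and Cxcl6 fell 9.35-fold and 21.5-fold, the growth factor-binding protein gene Igfbp3 fell 37.1-fold, and the matrix protease gene Mmp3 fell 96.7-fold. Spp1, encoding osteopontin, was among those that rose. The camera test called the list lower (adjusted p = 1.6e-12, and adjusted p = 0.028 with an estimated correlation).

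Mitophagy genes moved in both directions. Of 33 tested genes, 16 rose and 15 fell, and 31 passed when adjusted over the list alone. Pink1, the kinase that marks damaged mitochondria, fell 2.51-fold from 64.6 ± 5.42 to 25.8 ± 2.52 CPM (edgeR adjusted p = 1.8e-11). Autophagy receptor genes Tax1bp1 and Optn rose 8.28-fold and 2.84-fold, the deubiquitinase gene Usp15 rose 20.9-fold, and Rb1cc1, a scaffold of the autophagy-initiating kinase complex, rose 8.55-fold. The mitochondrial receptor gene Fkbp8 fell 3.4-fold, Nipsnap1 fell 5.17-fold and Vdac1, a channel of the outer membrane, fell 2.28-fold. Bnip3 fell 1.28-fold and Sqstm1, encoding p62, rose by 0.33 on the log2 scale. As a set the list was not called against other genes (camera adjusted p = 0.82).

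Of 44 autophagy and lysosome genes, 27 fell and 14 rose, with a median log2 change of -0.51, and 41 passed when adjusted over the list alone. Map1lc3a, encoding the autophagosome protein LC3A, fell 4.39-fold, and the lysosomal genes Ctsd, Psap and Ctsb fell 2.43-fold, 2.41-fold and 1.96-fold. Uvrag, a subunit gene of the lipid kinase complex of autophagy, rose 5-fold and had the smallest p of the list, and Lamp2 rose 1.71-fold. The list was not called by camera (adjusted p = 0.089), although it was called without young replicate 2 (adjusted p = 0.041) and with no low-count filter (adjusted p = 0.031).

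Cytosolic DNA sensing also showed no single direction. Of 30 tested genes of the sensing pathway and its nucleases, 19 fell and 10 rose, and 29 passed when adjusted over the list alone. Cgas, the DNA sensor, rose 5.49-fold from 1.87 ± 0.378 to 10.2 ± 0.479 CPM, and its adaptor Sting1 rose 5.96-fold from 0.518 ± 0.167 to 3.11 ± 0.147 CPM. The downstream kinase gene Tbk1 rose 3-fold, whereas its relative Ikbke fell 6.8-fold, the transcription factor gene Irf3 fell 2.17-fold, and Nfkb1 fell 2.86-fold. Trex1, a DNA exonuclease gene, rose 1.27-fold and Dnase2, the lysosomal DNase gene, fell 2.46-fold. Nlrp3, an inflammasome sensor, fell 22-fold from 130 ± 1.51 to 5.87 ± 0.641 CPM, the smallest p of the list. The list had a median log2 change of -0.61 and was not called against other genes (camera adjusted p = 0.17).

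Interferon-stimulated genes were not raised as a group. Of 37 tested genes, 21 fell and 12 rose, with a median log2 change of -0.81, and 33 passed when adjusted over the list alone. Ifi27 fell 3.32-fold, Ifi35 fell 19.3-fold and Isg15, a ubiquitin-like modifier at 0.637 ± 0.0977 CPM in young cells, fell 2.69-fold. Eif2ak2, encoding the double-stranded RNA-activated kinase PKR, rose 14.6-fold, and Ifih1, encoding the RNA sensor MDA5, rose 3.64-fold. The chemokine gene Cxcl10 rose from 0.198 ± 0.132 to 1.09 ± 0.382 CPM. The camera test did not call the list (adjusted p = 0.43), and 10 listed genes in the file, including Mx2, Oas2 and Rsad2, were too low to test.

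**Figure D2:**
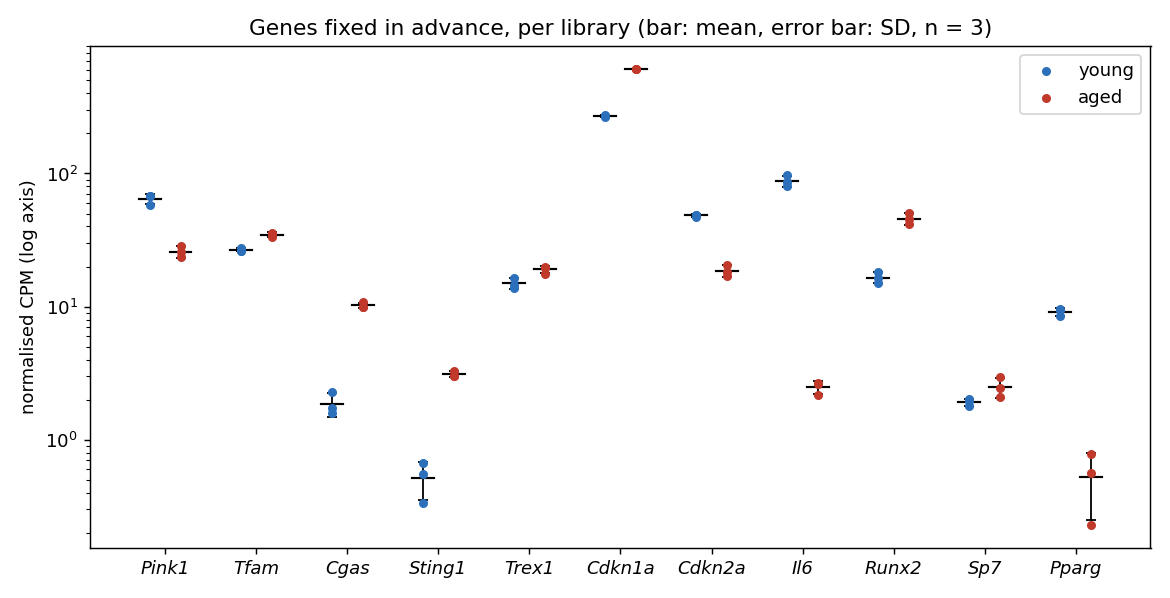
Normalised CPM on a log axis of genes chosen in advance in each of the 3 young (blue) and 3 aged (red) libraries, with mean and SD bars. Cgas, Sting1, Cdkn1a and Runx2 lie higher in aged libraries, and Pink1, Cdkn2a, Il6 and Pparg lie lower.

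Osteoblast genes were divided. Of 23 tested genes, 10 rose and 8 fell, and 17 passed when adjusted over the list alone. Runx2, the transcription factor gene that commits cells to bone, rose 2.78-fold from 16.5 ± 1.57 to 45.8 ± 4.54 CPM. Spp1 rose 9.06-fold to 1712 ± 18.6 CPM, and Tnfrsf11b, encoding the osteoclast inhibitor osteoprotegerin, rose 5.49-fold. Col1a1, encoding the main bone collagen, fell 1.79-fold from 19586 ± 202 to 10932 ± 41.6 CPM, and Dlx3 fell 8.91-fold. Sp7, encoding osterix, had 1.92 ± 0.112 and 2.5 ± 0.43 CPM and was not called (edgeR adjusted p = 0.11), and nor was the alkaline phosphatase gene Alpl at 6.82 ± 0.323 and 6.71 ± 1.21 CPM (edgeR adjusted p = 0.87). As a set the list was not called against other genes (camera adjusted p = 0.78).

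Adipocyte genes were lower in aged cells, with 26 of 30 tested genes lower and 3 higher, a median log2 change of -2.20, and 29 passing when adjusted over the list alone. Pparg, the master transcription factor gene of fat cells, fell 17.6-fold from 9.17 ± 0.627 to 0.523 ± 0.275 CPM, and Cebpa fell 4.07-fold. Besides Fabp4, the triglyceride synthesis gene Dgat2 fell 14.6-fold, the lipid droplet gene Plin1 fell 136-fold, and the lipoprotein lipase gene Lpl fell 6.91-fold. Fasn, encoding fatty acid synthase, fell only 1.26-fold. The camera adjusted p was 1.4e-09, and the call was lost at adjusted p = 0.072 with an estimated correlation.

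Chondrocyte genes did not move together, with 8 of 16 tested genes higher and 4 lower, and 12 passing when adjusted over the list alone. Besides Prg4, Col11a1 rose 2.74-fold and Sox9, the cartilage transcription factor gene, fell 2.22-fold. The list median was 0.64 and its mean 0.05, whereas camera gave a lower direction with adjusted p = 0.97. Stromal markers were also mixed, with 16 of 33 lower, 12 higher and 28 passing when adjusted over the list alone. Cxcl12, the chemokine gene that retains blood stem cells in the marrow, fell 16.7-fold from 3387 ± 165 to 203 ± 1.44 CPM. The surface marker gene Thy1 fell 2.61-fold, Nt5e, encoding CD73, rose 4.48-fold, and Eng, encoding CD105, was not called. This list was not called (camera adjusted p = 0.079), but it was without young replicate 1 (adjusted p = 0.044) or without young replicate 2 (adjusted p = 0.014) and with no low-count filter (adjusted p = 0.028).

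Matrix genes fell as a group. Of 46 tested genes of collagens and other matrix, 38 fell and 7 rose, with a median log2 change of -1.24, and 45 passed when adjusted over the list alone. Thbs2, encoding thrombospondin 2, fell 4.68-fold from 7879 ± 57.3 to 1682 ± 1.84 CPM, the fibronectin gene Fn1 fell 2.31-fold, the fibrillin gene Fbn1 fell 8.63-fold and Mgp, an inhibitor of calcification, fell 20.2-fold. The proteoglycan gene Ogn rose 51.5-fold, and Plod2, encoding a collagen lysyl hydroxylase, rose 3.15-fold. Camera gave adjusted p = 1.2e-14, and adjusted p = 0.049 with an estimated correlation. Among 37 Wnt and BMP genes, 21 fell and 11 rose, and 32 passed when adjusted over the list alone. The Wnt receptor gene Fzd1 fell 5.27-fold, the Wnt antagonist gene Sfrp2 fell 842-fold, Wnt5a fell 2.87-fold, and the BMP receptor gene Bmpr2 rose 9.92-fold. Camera called this list lower (adjusted p = 0.029), but not with an estimated correlation (adjusted p = 0.15) or with limma-voom (adjusted p = 0.16), and its median of -0.32 became 0.02 when scaled by library size alone.

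Transcripts encoded by mitochondrial DNA were higher in aged cells, and nuclear genes of oxidative phosphorylation were lower. Of the 13 mitochondria-encoded genes, 11 rose and 2 fell, with a median log2 change of 1.78, and all 13 passed when adjusted over the list alone. ND4L and ATP6 rose 7.29-fold and 6.49-fold, COX1 rose 3.44-fold to 14286 ± 398 CPM and CYTB rose by 0.33 on the log2 scale, whereas ND6 fell 5.72-fold and ND3 fell 1.64-fold. Of 77 nuclear genes, 74 fell and 0 rose in edgeR (70 lower and 4 higher when scaled by library size alone), with a median log2 change of -0.93, and 74 passed when adjusted over the list alone. The ATP synthase genes Atp5mc2 and Atp5f1b fell 3.38-fold and 2.11-fold, and the complex IV gene Cox4i1 fell 1.68-fold. Camera called the mitochondrial list higher (adjusted p = 4.6e-04) and the nuclear list lower (adjusted p = 1.3e-09), and neither call held with an estimated correlation (adjusted p = 0.45 and adjusted p = 0.22). Cytosolic ribosomal protein genes, examined after the data were seen, fell by a median of 1.31 on the log2 scale. The rise of the mitochondria-encoded genes was not tested apart from the pattern of long transcripts above.

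Genes of mitochondrial dynamics, biogenesis and DNA upkeep were not called as a set (camera adjusted p = 0.17), with 22 of 38 higher, 10 lower and 32 passing when adjusted over the list alone. Hspa9, the mitochondrial chaperone mortalin, rose 4.4-fold, the fission gene Dnm1l rose 11.1-fold and the fusion gene Opa1 rose 3.74-fold, whereas the fission gene Fis1 fell 2.33-fold. Tfam, encoding the factor that packages mitochondrial DNA, rose 1.3-fold from 26.7 ± 0.702 to 34.7 ± 1.36 CPM (edgeR adjusted p = 2.6e-05). Antioxidant genes were split, with 14 of 36 higher, 17 lower and 32 passing when adjusted over the list alone (camera adjusted p = 0.82). Hmox1, encoding heme oxygenase, rose 7.13-fold and the cystine transporter gene Slc7a11 rose 41.2-fold. Sod2, encoding the mitochondrial superoxide dismutase, fell 9.23-fold from 1337 ± 47.0 to 145 ± 6.55 CPM, and Gpx4 fell 2.55-fold. Of 31 glycolysis and hypoxia genes, 23 fell and 7 rose, with a median log2 change of -1.06, and 30 passed when adjusted over the list alone. Egln3, encoding an oxygen-sensing hydroxylase, fell 41.5-fold, the lactate exporter gene Slc16a3 fell 7.28-fold and Pgk1 fell 3.83-fold, while Hif1a rose 4.33-fold. The camera adjusted p was 1.9e-07, and the call was lost at adjusted p = 0.14 with an estimated correlation.

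Genes of the unfolded protein and integrated stress responses rose together. Of 31 genes, 24 rose and 4 fell, with a median log2 change of 0.99, and 28 passed when adjusted over the list alone. Hspa5, encoding the endoplasmic reticulum chaperone BiP, rose 10.7-fold from 506 ± 9.13 to 5386 ± 85.7 CPM. Hsp90b1, encoding GRP94, rose 18-fold, the disulfide isomerase gene Pdia4 rose 3.89-fold and Ddit3, encoding CHOP, rose 2.71-fold, whereas Xbp1 fell 2.76-fold. Camera gave adjusted p = 1.9e-07, and adjusted p = 0.049 with an estimated correlation. Of 30 immediate-early and heat shock genes, 17 fell and 10 rose, and 27 passed when adjusted over the list alone. Nr4a1, an inducible nuclear receptor gene, fell 68.8-fold and Egr1 fell 4.09-fold, whereas Hsp90aa1 rose 12.2-fold and Fos was not called, at 9.37 ± 1.32 and 8.81 ± 0.406 CPM (camera adjusted p = 0.11 for the list, and 0.043 with no low-count filter). Among 44 genes of DNA damage response and repair, 22 fell and 19 rose, and 41 passed when adjusted over the list alone. H2ax, a histone variant gene, fell 6.53-fold, while the damage kinase genes Atm and Atr rose 17.3-fold and 13-fold and the ligase gene Lig4 rose 20.9-fold. The rises of Hspa5, Hsp90b1, Pdia4, Ddit3, Atm, Atr and Lig4 lie within the range of the long transcripts above and were not tested apart from it. The median of that list was -0.17 (0.16 when scaled by library size alone) and its mean 0.23, and camera did not call it (adjusted p = 0.82).

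**Figure D3:**
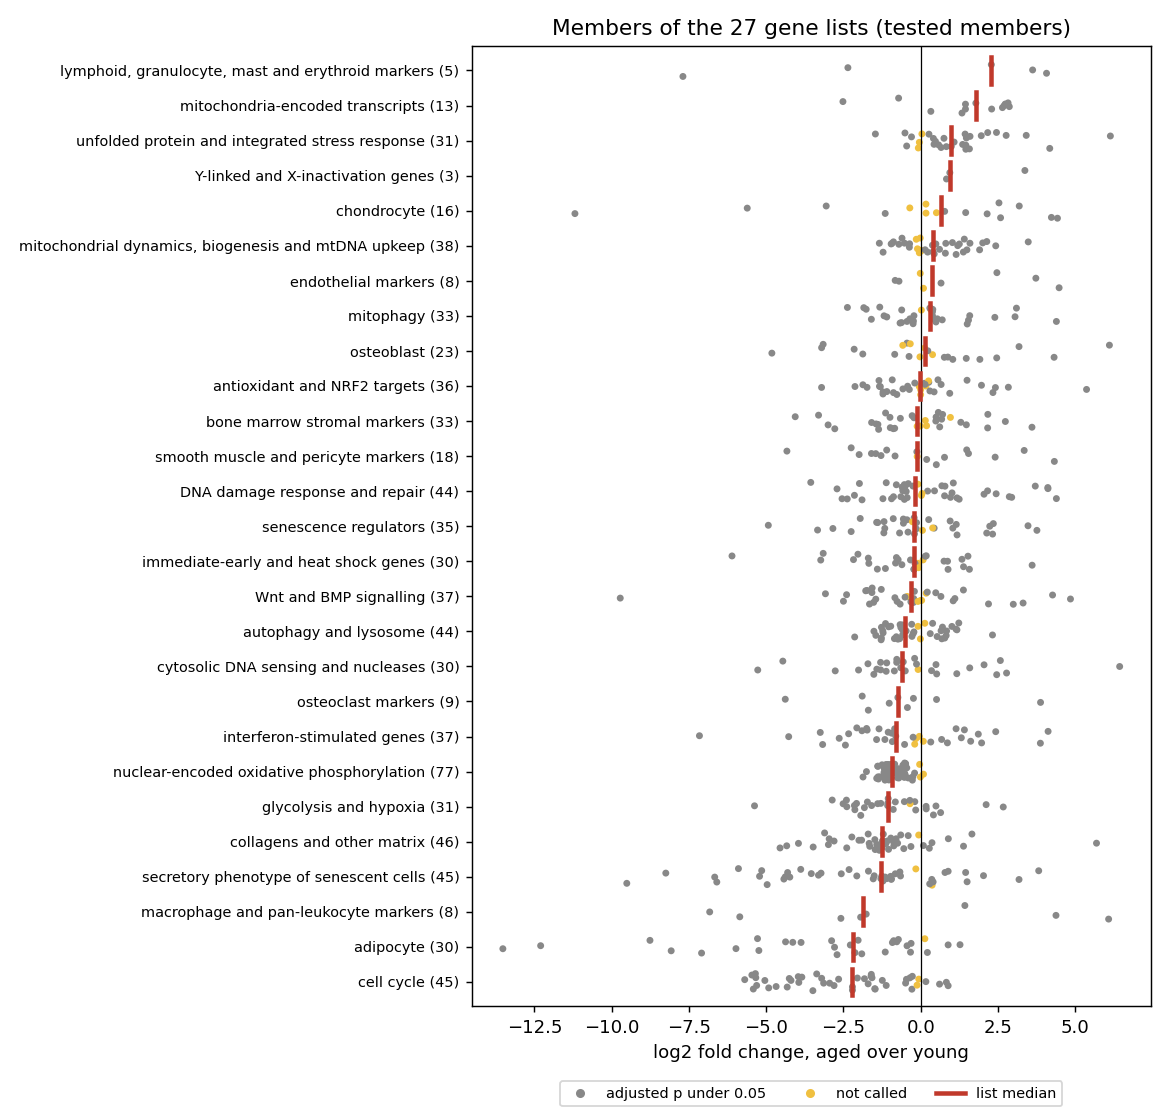
Log2 fold change (aged over young, edgeR fit) of the tested members of the 27 gene lists, with the number tested in brackets, called members in grey, members not called in yellow and list medians as red bars. The cell cycle and adipocyte medians lie lowest, at -2.21 and -2.20, the mitochondria-encoded median lies at 1.78, and folds of genes at 0 counts in a group are fitted values.

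Many markers of other cell types were too low to test. Of 31 macrophage and leukocyte genes in the file only 8 could be tested, with 5 lower and 3 higher, and all 8 passed when adjusted over the list alone. Ptprc, the pan-leukocyte marker CD45, had 0 young counts and 1 aged count in all. Cd14 fell 3.85-fold from 80.7 ± 0.772 to 21 ± 0.6 CPM, the lysozyme gene Lyz2 fell 57.8-fold, and Csf1r, a receptor of macrophages, rose 67.5-fold to 21.8 ± 0.552 CPM (list: camera adjusted p = 0.51). Of 9 osteoclast genes, 7 fell and 2 rose, all 9 passing when adjusted over the list alone, with Mmp9 down 20.8-fold and Ctsk down 3.24-fold (camera adjusted p = 0.079). Only 5 lymphoid, granulocyte, mast and erythroid genes were tested, 3 higher and 2 lower, all 5 passing when adjusted over the list alone. The myeloperoxidase gene Mpo fell from 10.7 ± 0.359 to 0.0503 ± 0.0513 CPM, the list median was 2.28 and its mean -0.01, and camera gave adjusted p = 0.82. Of 8 endothelial genes, 4 rose and 2 fell, 6 passing when adjusted over the list alone, and Egfl7 fell 1.77-fold (camera adjusted p = 0.90). The endothelial genes Pecam1 and Cdh5 were too low to test, with 4 and 1 counts in young libraries and 2 and 0 in aged ones. Of 18 smooth muscle and pericyte genes, 8 rose and 9 fell, 17 passing when adjusted over the list alone, with Tpm2 down 3.02-fold, the smooth muscle regulator gene Myocd up 10.2-fold and Acta2 up 1.42-fold (camera adjusted p = 0.82). The Y-linked genes Kdm5d, Eif2s3y and Uty were present in all 6 libraries and rose 1.78-fold, 1.92-fold and 10.3-fold in aged cells, all 3 passing when adjusted over the list alone, and Xist had at most 12 counts in a library.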

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

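The fits without the 13 mitochondria-encoded genes and without the 20 most abundant genes were chosen after seeing the data. Over all alternatives, the named genes kept their direction and side of the threshold in 906 comparisons, with 0 reversed, and Sp7 passed with library size only (log2 change 0.72, edgeR adjusted p = 0.0053). The 2-fold requirement left 4200 higher and 3000 lower genes, because it adds a criterion. Leaving out 1 library gave 6241 to 6565 higher and 5870 to 6012 lower genes. With library size only, 258 of the 12339 called genes were called in the opposite direction and 1052 were not called. Replicate numbers showed no sign of a pairing. Libraries of the same number had correlations of deviations of -0.013, 0.0011 and 0.0098, and not every library correlated best with its own number. That cannot exclude that the numbers mark something shared, which the labels do not state. The replicate block gave 6279 higher and 5883 lower genes.

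For the lists, fry passed 25 of 26, among them mitophagy (adjusted p = 0.0052), DNA sensing (3.2e-05), interferon-stimulated (6.8e-05), senescence regulator (6.8e-05) and osteoblast genes (4.2e-04), because it tests a list without comparing it with other genes. The adipocyte call was lost with an estimated correlation (adjusted p = 0.072, range over alternatives 3.0e-12 to 0.072). The direction reversed without a call for chondrocyte genes with no filter (adjusted p = 0.987), with limma-voom (0.456) and without single libraries (0.921 to 0.975). It also reversed for lymphoid (0.930) and DNA repair genes (0.930) with limma-voom, for endothelial genes with library size only (0.984) and with the CPM filter (0.976), and for antioxidant genes with library size only (0.775), and the cause was not tested. Genes under 0.0688 to 0.0840 CPM are beyond the depth of these libraries.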

Other observations

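All gene groups in the next paragraph and the lists of long transcripts were chosen after the data were seen. So were the tests of the cell cycle list, of other splits of the samples and of the shares of counts.

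Cytosolic ribosomal protein genes (symbols Rpl or Rps, like-named copies included) were lower in aged cells, with 85 of 90 lower, 3 higher and a median log2 change of -1.31 (95% bootstrap interval -1.36 to -1.26). Rpl3 fell 7.8-fold, Rplp0 fell 2.13-fold and Rps6 only 1.12-fold (camera adjusted p = 5.7e-27, and adjusted p = 0.15 with an estimated correlation). Genes with Mrpl or Mrps symbols, mostly of the mitochondrial ribosome (53 of 77 lower, 11 higher), and proteasome subunit and assembly genes (29 of 37 lower, 7 higher) also fell, with medians of -0.72 and -0.52 (camera adjusted p = 0.0078 and 0.031, and adjusted p = 0.25 and 0.24 with an estimated correlation). Zinc-finger genes named Zfp or Znf rose in 219 of 289 cases and fell in 40, and centrosomal protein genes named Cep rose in 29 of 39 and fell in 7, with medians of 1.44 and 1.33 (camera adjusted p = 3.8e-08 and 5.4e-04, and adjusted p = 0.072 and 0.15 with an estimated correlation). A list of targets of the aryl hydrocarbon receptor, drawn up because of Cyp1a1, had 5 of 6 genes higher and 1 lower, and was not called. Tiparp rose 9.09-fold, Cyp1b1 4.26-fold and the repressor gene Ahrr 2.67-fold, whereas Aldh3a1 fell 25-fold (camera adjusted p = 0.0501, and adjusted p = 0.20 with an estimated correlation). Of 22 cholesterol synthesis and uptake genes, 12 fell and 7 rose, with Srebf2 down 3.11-fold and Sc5d up 2.35-fold (camera adjusted p = 0.19).

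The difference between the groups covered most genes, with 12339 called. Of the 10 splits of the 6 libraries, 1, the real one, called as many, and the highest other split called 0. Every other split had young and aged libraries on both sides, so the group difference widened the spread within each side. These splits, also too few for a share under 0.05, therefore cannot tell whether the grouping arose by chance. The 20 most abundant genes are argued against as the cause, since their share of the counts changed the share left to other genes by only 0.0398 on the log2 scale, against a median absolute change of 1.2 among called genes. A list of 35 long transcripts thought to be of low GC content rose by a median of 3.53 (camera adjusted p = 4.3e-31, and adjusted p = 0.072 with an estimated correlation), and 32 long ones thought to be of high GC content had a median of -0.62 (bootstrap interval -0.89 to -0.45, camera adjusted p = 5.4e-04, and adjusted p = 0.35 with an estimated correlation). The difference of the medians, 4.15 (3.86 to 4.89), is what a GC-dependent difference between the libraries would give. Length alone would move both lists of long transcripts the same way. Their opposite medians argue against it for these lists, although 7 of the 32 genes of the high-GC list rose and 25 fell. The lists also differ in abundance. Young CPM reached 3457 (Lrp1) in the high-GC list, though Celsr2 had 0.238, and 56.2 (Rock2) in the low-GC list. The gap therefore cannot tell GC content from abundance. GC content and length come from general knowledge there, and age and any library difference that coincides with age both stay open.

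Mitochondria-encoded genes rose and nuclear oxidative phosphorylation genes fell. The larger mitochondrial share of the counts is argued against as the cause of the nuclear fall, since that share changed the share left to other genes by a log2 value of only -0.0467 (-0.0503 to -0.0428 over pairs of libraries), against the list median of -0.93. A general fall of short, abundant nuclear transcripts remains a candidate explanation, because the ribosomal protein genes, a class with no part in respiration, had a median of -1.31. A change with age in the nuclear genes was not tested apart from it. Nor was the rise of the mitochondria-encoded genes, with a median of 1.78, tested apart from the rise of the low-GC list above.

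The cell cycle list had a median log2 change of -2.21 (bootstrap interval -3.49 to -1.60), further than the ribosomal protein genes. Its 7 members thought to have long transcripts of low GC content had a median of -1.60 (-2.66 to -0.27), opposite to the 35 genes above, with Cenpe the 1 that rose. Library differences by GC content or abundance cannot be told apart from an age effect here, because those 7 members were picked after their values were seen and such differences need not be of one size. A lower rate of division in the aged cultures may also account for the fall and was not tested.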
